A study of Mus musculus with 8 samples.

How the data were processed

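Total spleen RNA of 4 wild-type and 4 TTPΔARE mice was sequenced, and the deposited values are FPKM per RefSeq transcript and sample, made by the authors. Reads were aligned with BWA to mm10, per the submitters' processing notes. The counting tool, annotation release, strand setting, treatment of reads that match several places and any filter are not given in the sources used here. The groups were taken from the genotype labels, which give no batch, litter or pairing. The table has 23517 transcripts of 17738 symbols, of which 9324 share a symbol with another transcript, and none is at 0 in every sample. Accessions matched the RefSeq gene table of GRCm38.p6 for 23092 transcripts, which gave coordinates of whole genes, and 21875 had a 3′ UTR in GENCODE M21.

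FPKM are not counts, so no count model was used. Depth was estimated from the steps between values of at most 0.5 FPKM: at the best depth 40.7 to 45.8% of them were whole fragments within 0.05, against 8.1 to 10.4% at a wrong depth. The estimates were 28.3 to 32.2 M fragments. At the lowest, 0.5 FPKM on a transcript of 2664 bases, the median length, stands for about 37.7 fragments. Most low values were not whole, so fragment counts were not rebuilt. Summed FPKM per sample were 196913 to 215501.

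Transcripts with a mean of at least 0.5 FPKM over the 8 samples, 16608 in all, were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low transcripts. Zfp36 was also tested by an exact permutation test. Gene lists were tested with camera at a preset correlation of 0.01, with 1 transcript per symbol, that of the highest mean, and with at least 3 measured members. Of 30 lists with 868 symbols, 830 symbols were found and 29 lists could be tested. The lists were the TTP family, reported TTP targets, cytokines, immediate early genes, NF-κB, interferon-stimulated genes, mRNA decay, AU-rich element binding proteins, heme and globins, cell cycle, ribosomal proteins, oxidative phosphorylation, stress, genes near Zfp36, sex-linked genes and markers of spleen cell types, pancreas and adipose tissue. AU-rich sets were genes with at least 2 TATTTAT heptamers or at least 1 TTATTTATT nonamer in the longest annotated 3′ UTR, against other tested genes with a 3′ UTR.

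Named genes are Zfp36, Zfp36l1 and Zfp36l2, the 10 largest rises and 10 largest falls among transcripts past the threshold with a mean of at least 1 FPKM and no overlap between groups (predicted genes and pseudogenes left out), and up to 4 members per list: the 3 with the smallest p and the 1 with the highest mean. Not every gene that this rule takes is named in the text. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined. Flt3, Tnfsf14, Sox18, Kdr, Dcn, Hbb-b2, Plaur and Stac2 were named after their values were seen, to complete small counts, as were the genes of the other observations.

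Alternatives were other pseudocounts and filters, median-of-ratios and quantile scaling, no variance trend, a robust variance, sample weights, an erythroid covariate, a threshold of 0.1, other list tests, a heptamer minimum of 1 and leaving out each sample. Using 1 transcript per symbol and a permutation test of list means were added after seeing the data. The limma step was tested on simulated data for this comparison with 16608 transcripts, 50 changed at each fold: it recovered 42% at 1.3-fold, 88% at 1.5-fold, 98% at 2-fold and 98% at 3-fold, and 11 of 174 calls, 6.3%, were false. At an unadjusted p under 0.05 camera called 20 of 20 simulated lists of 25 genes shifted by log2 0.5, and 2 of 20 unshifted ones. The simulated genes varied independently, so this does not show how often camera makes false calls on lists of correlated genes. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.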

Results

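Spleens of 8 male C57BL/6 mice aged 8 to 12 weeks were profiled by RNA sequencing, 4 wild-type and 4 carrying the TTPΔARE allele. Tristetraprolin (TTP), encoded by Zfp36, binds AU-rich elements in the 3′ untranslated region (3′ UTR) of mRNAs and promotes their decay, and the TTPΔARE allele lacks such an element in the Zfp36 mRNA itself. The comparison asked which spleen mRNAs differed between the genotypes. Expression was given as FPKM, fragment counts scaled for transcript length and sequencing depth, for 23517 RefSeq transcripts of 17738 gene symbols. The depth recovered from the steps between low values was 28.3, 31.4, 29.3 and 32.2 M fragments for wild-type replicates 1 to 4 and 32.2, 29.1, 31.7 and 32.2 M for the TTPΔARE replicates, and each spleen was 1 animal.

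Zfp36 mRNA was higher in TTPΔARE spleens. The level rose from 40.3 ± 3.91 FPKM in wild-type to 52.9 ± 4.90 FPKM in TTPΔARE (SD, n = 4 each), a 1.31-fold rise (log2 0.39, SE 0.0848, limma adjusted p = 0.0323). The wild-type values spanned 36.4 to 44.9 FPKM and the TTPΔARE values 46.1 to 57.5 FPKM, without overlap, and an exact two-sided permutation test over the 70 assignments gave p = 0.0286, the smallest it can give. Zfp36 lies on chromosome 7 at 28376784 to 28379228 (GRCm38/mm10). Reads of the deleted part of the 3′ UTR cannot occur in TTPΔARE samples while FPKM divides by the annotated transcript length, so the measured rise does not include that part. The limma call was lost without wild-type replicate 1 (adjusted p = 0.0665), wild-type replicate 4 (0.0918), TTPΔARE replicate 1 (0.0734), TTPΔARE replicate 3 (0.108) or TTPΔARE replicate 4 (0.0862), and with an erythroid covariate (log2 0.28, adjusted p = 0.386). The related Zfp36l1 fell 1.43-fold, from 101.6 ± 3.91 to 71.0 ± 5.32 FPKM (log2 -0.52, adjusted p = 0.00461). Zfp36l2 stood at 46.6 ± 3.06 and 35.9 ± 7.06 FPKM (log2 -0.39) and did not pass (adjusted p = 0.0764), though without TTPΔARE replicate 3 it did (log2 -0.52, adjusted p = 0.0137).

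**Figure D1:**
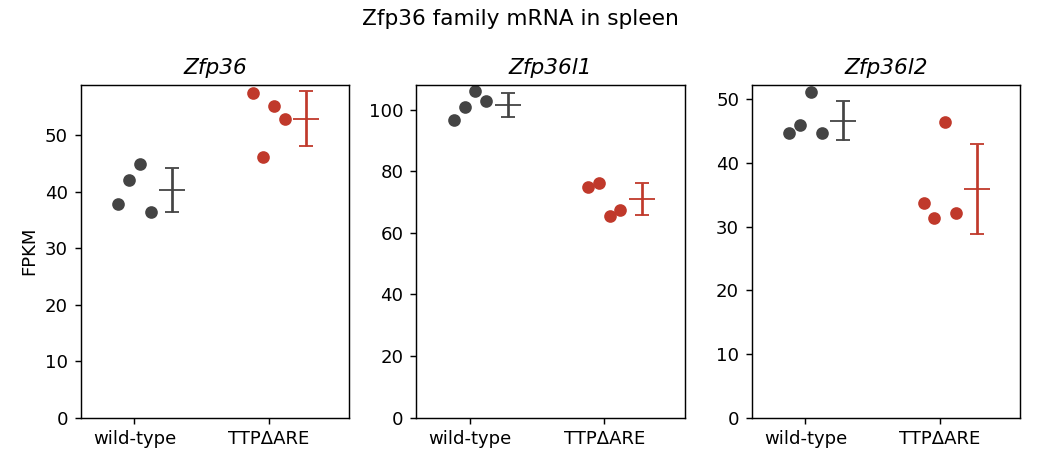
FPKM (y axis, linear from 0) of Zfp36, Zfp36l1 and Zfp36l2 in 4 wild-type (grey) and 4 TTPΔARE (red) spleens, each point a spleen, with the group mean and SD beside the points. Zfp36 was higher in all 4 TTPΔARE spleens and Zfp36l1 lower in all 4, while the highest TTPΔARE value of Zfp36l2, 46.4 FPKM, lay among the wild-type values.

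Globin and heme genes, the chemokine Ccl24, the chitinase-like Chi3l1 and the neutrophil collagenase Mmp8 were among the transcripts with the largest rises in TTPΔARE spleen, and the chemokine receptor Ccr6, the fatty acid receptor Ffar1 and the lymphoid chemokine Ccl21a among those with the largest falls. Ccl24 rose from 1.03 ± 0.267 to 3.38 ± 0.482 FPKM (SD, n = 4 each; log2 1.35, SE 0.135, limma adjusted p = 0.00248), and Chi3l1 from 0.574 ± 0.156 to 2.17 ± 0.634 FPKM (log2 1.29). The apolipoprotein L gene Apol11b had the largest rise, log2 1.83 with an SE of 0.419, from 3.64 ± 0.885 to 17.1 ± 12.2 FPKM. Tnn, which encodes the matrix protein tenascin N, fell by 1.02 on the log2 scale, and Ffar1 fell by 1.01, from 9.87 ± 1.69 to 4.66 ± 1.02 FPKM. Ccr6 had 3 transcripts among the largest falls, which went from 2.53 ± 0.437 to 1.03 ± 0.375, from 3.42 ± 1.06 to 1.49 ± 0.390 and from 2.33 ± 0.395 to 1.02 ± 0.286 FPKM. The desmosomal cadherin Dsc3 fell from 1.82 ± 0.211 to 0.680 ± 0.246 FPKM. On the log2 scale the BMP antagonist Grem1 fell by 0.93, the endothelial adhesion molecule Madcam1 fell by 0.91, Ccl21a fell by 0.98 and Ccl21b fell by 0.88. Ccl21 copies share near-identical sequence, as do the α-globin and β-globin paralogs, so the split of reads within each family is uncertain.

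In all, 333 transcripts rose and 331 fell among 16608 tested (limma, adjusted p under 0.05), which belong to 308 and 254 gene symbols. At an unadjusted p under 0.05 there were 3503. Changes were small: the median absolute log2 change of the 664 was 0.41, 1.33-fold, and 17 rose and 4 fell at least 2-fold. The groups did not overlap at all for 2079 of the tested transcripts, 12.5% against 2.86% by chance. Globin transcripts took 3.03 to 5.53% of summed FPKM in wild-type and 7.19 to 10.3% in TTPΔARE samples. With the mean of the erythroid list as a covariate, only Plaur and Stac2 passed, both lower (limma, with 1744 at an unadjusted p under 0.05). Without wild-type replicate 4, TTPΔARE replicate 3 or TTPΔARE replicate 4 the counts were 114 higher and 138 lower, 94 and 104, and 118 and 136.

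**Figure D2:**
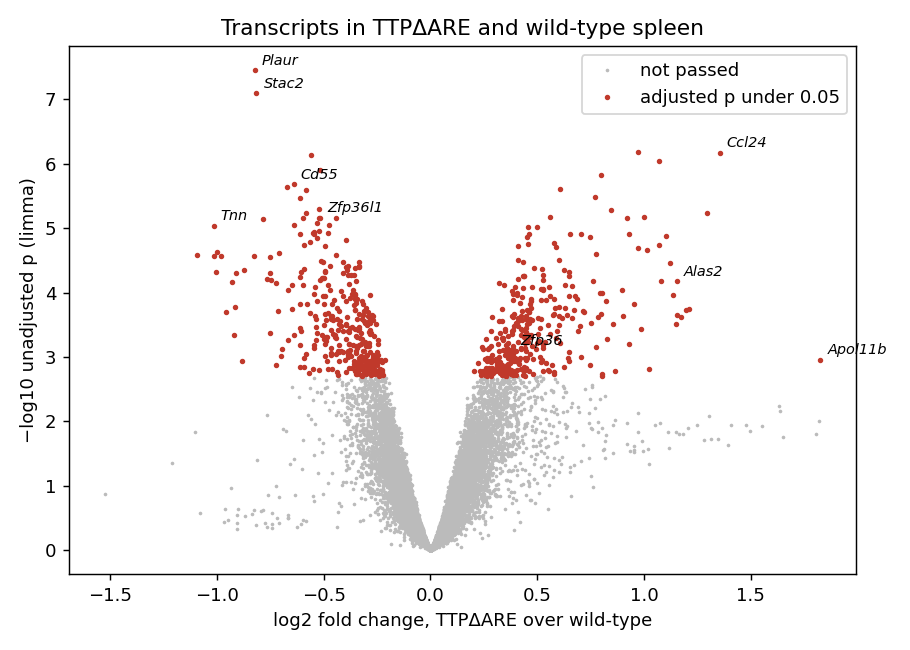
Log2 fold change of TTPΔARE over wild-type (x axis) against −log10 of the unadjusted limma p (y axis) for 16608 transcripts, with those at an adjusted p under 0.05 in red. Rises and falls were about equal in number, 333 and 331, and Apol11b had the largest rise among the red points.

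Of 20 heme and globin genes tested, 7 rose and 13 did not pass: Alas2, the first enzyme of erythroid heme synthesis, from 24.7 ± 6.39 to 55.5 ± 13.03 FPKM (SD, n = 4 each; log2 1.15), Fech, the last enzyme, from 14.3 ± 2.05 to 26.0 ± 5.74 FPKM (log2 0.82), Hba-a1 and Hba-a2 (log2 1.20 and 1.21), Hbb-b1 and Beta-s (1.16 and 1.15) and Hbb-b2 (1.02). With quantile normalization, which sets the most abundant transcripts to near-equal values, Hba-a1, Hba-a2 and Beta-s stood at 0.13, 0.29 and 0.14 and did not pass (adjusted p = 0.221, 0.0851 and 0.330), nor did Hbb-b2 (log2 0.999, adjusted p = 0.0542), which lost its call in 6 of 10 processing alternatives. The list median was 0.80 (camera adjusted p = 1.91e-10, adjusted p = 0.528 with an estimated correlation), and 15 rose when adjusted over the list alone. A second Alas2 transcript rose by log2 1.14. Hbb-b2 stood at only 1.74 ± 0.762 and 3.89 ± 0.941 FPKM in wild-type and TTPΔARE, against 2742.2 ± 854.1 and 5959.7 ± 1265.3 FPKM for Beta-s. The split of reads between these paralogs is uncertain, so Hbb-b2 may not be a separate rise. Among 27 erythroid markers all 27 had a positive value and the median was 1.18, 2.27-fold (camera adjusted p = 4.23e-11, adjusted p = 0.538 with an estimated correlation). Only Bpgm, the red cell bisphosphoglycerate mutase, passed over all transcripts, from 35.9 ± 11.04 to 70.1 ± 13.1 FPKM, and 24 rose when adjusted over the list alone. Car2 and Cldn13 had log2 values of 1.63 and 1.64 with SEs of 0.481 and 0.495 and did not pass. The per-sample erythroid means overlapped, since wild-type replicate 3 stood 1.18 above the wild-type mean and the TTPΔARE spleens 0.55 to 1.58 above it (exact permutation p = 0.0857). Of 18 megakaryocyte and platelet genes 2 rose, the integrin Itgb3 (log2 0.65) and Treml1 (0.75), and 11 when adjusted over the list alone, with a median of 0.51 (camera adjusted p = 4.02e-07, adjusted p = 0.538 with an estimated correlation). Ppbp (log2 0.58) did not pass.

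Of 18 B cell genes tested, 3 fell and 15 did not pass: the low-affinity IgE receptor Fcer2a from 18.4 ± 0.802 to 12.0 ± 1.25 FPKM (SD, n = 4 each; log2 -0.60), the inhibitory receptor Cd22 from 57.8 ± 4.68 to 38.9 ± 3.63 FPKM (log2 -0.57) and H2-Ob (log2 -0.32). Cd79b had a log2 value of -0.27 and did not pass. The list median was -0.18 (camera adjusted p = 8.94e-07, adjusted p = 0.528 with an estimated correlation), and 9 fell and 1 rose when adjusted over the list alone. The erythroid and globin lists were higher in the same samples. Of 9 plasma cell genes only Txndc5 fell (log2 -0.61), with Sdc1 at -0.49, Fkbp11 at -0.54 and Igj at -0.41 not passing and 3 falling when adjusted over the list alone (median -0.28, camera adjusted p = 0.00557, adjusted p = 0.559 with an estimated correlation). Without wild-type replicate 1 Fkbp11 was at -0.34 and Igj at -0.15. The plasma cell median was -0.15 without wild-type replicate 1 and -0.45 without wild-type replicate 2. By limma 0 of 21 T cell genes passed, over all transcripts or adjusted over the list alone, with 7 at an unadjusted p under 0.05. Cd6, Cd5, Cd3d and Tcf7 had log2 values of -0.24, -0.31, -0.24 and -0.21, and the list median was -0.09 (camera adjusted p = 0.0361, adjusted p = 0.658 with an estimated correlation). The T cell call was lost without wild-type replicate 1, 2 or 4 or TTPΔARE replicate 2 or 4 (adjusted p = 0.0982, 0.0953, 0.0910, 0.0532 and 0.216) and with quantile normalization (0.109), and its median was -0.05 without wild-type replicate 1 and -0.04 without TTPΔARE replicate 4.

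Of 17 dendritic cell genes tested, 4 rose and 13 did not pass: Esam from 5.89 ± 0.367 to 8.00 ± 0.502 FPKM (SD, n = 4 each; log2 0.41), the integrin Itgae (0.56), the chemokine receptor Xcr1 (0.53) and the cytokine receptor Flt3 (0.33), while H2-Aa stood at 0.01. The median was 0.33 (camera adjusted p = 3.78e-06, adjusted p = 0.528 with an estimated correlation), and 10 rose when adjusted over the list alone. Of 16 endothelial and sinusoid genes 4 rose (Esam, which is on both lists, Gpihbp1 with log2 0.67, Sox18 with 0.45 and Kdr with 0.36) and Madcam1 fell, while Plvap stood at 0.08. Their median was 0.23 (camera adjusted p = 3.89e-05, adjusted p = 0.528 with an estimated correlation), and 11 rose and 1 fell when adjusted over the list alone. Of 28 stress and heat shock genes 4 rose, the endoplasmic reticulum disulfide isomerase Pdia4 from 59.6 ± 2.50 to 79.2 ± 6.70 FPKM (log2 0.40) and the chaperones Hspb1 (0.83), Hsph1 (0.87) and Hspa8 (0.53), with a median of 0.17 (camera adjusted p = 0.000147, adjusted p = 0.528 with an estimated correlation). Adjusted over the list alone, 10 rose and 1 fell.

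Few members of the neutrophil, mast cell, macrophage and NK cell lists passed. Retnlg (log2 0.90) and Mmp8 (1.17) rose among 20 neutrophil genes, 3 when adjusted over the list alone, while Cd177 (0.69) and S100a9 (0.12) did not pass (median 0.26, camera adjusted p = 0.0169, adjusted p = 0.658 with an estimated correlation). The stem cell factor receptor Kit rose (log2 0.50) among 11 eosinophil, basophil and mast cell genes, 4 when adjusted over the list alone, with Gata2 at 0.24, Hdc at 0.62 and Ear2 at -0.05 not passing (median 0.28, camera adjusted p = 0.00491, adjusted p = 0.538 with an estimated correlation), and the median was 0.53 without wild-type replicate 3 and 0.44 without TTPΔARE replicate 2. Emr1, which encodes the macrophage protein F4/80, rose (log2 0.36) as 1 of 19 red pulp macrophage genes, and 1 when adjusted over the list alone, with Cd163, Cd68 and Vcam1 at 0.43, 0.26 and 0.31 not passing (median 0.15, camera adjusted p = 0.00759, adjusted p = 0.658 with an estimated correlation). Klra8 rose (log2 0.80) among 14 NK cell genes, 1 when adjusted over the list alone, with Txk at -0.23, Prf1 at 0.36 and Gzma at 0.20 (0.22 and -0.07 without TTPΔARE replicate 4) not passing (median 0.27, camera adjusted p = 0.0193, adjusted p = 0.658 with an estimated correlation). The Klra8 call (adjusted p = 0.0499) was lost in 7 of 10 processing alternatives and with 7 of the 8 spleens left out in turn, and TTPΔARE replicate 4 stood at 7.10 FPKM against 3.47 to 3.77 in the others of its group. Among 15 monocyte genes Ace (log2 -0.75), the lysozyme Lyz2 (-0.49) and Nr4a1 (-0.38) fell, 5 fell and 1 rose when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.266). Lyz2 fell from 652.5 ± 86.8 to 462.4 ± 16.3 FPKM (SD, n = 4 each). Camera calls were lost for the neutrophil list without wild-type replicate 1, 2 or 4 or TTPΔARE replicate 3 or 4 (adjusted p = 0.0705, 0.0781, 0.183, 0.102 and 0.0532), and its median was 0.65 without wild-type replicate 3, 0.15 without wild-type replicate 4 and 0.10 without TTPΔARE replicate 3. Those of the NK cell and red pulp macrophage lists were lost without wild-type replicate 4 (0.186 and 0.196) or TTPΔARE replicate 4 (0.260 and 0.0605), with medians of 0.14 for NK cells without TTPΔARE replicate 4 and 0.05 for macrophages without wild-type replicate 4.

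Cell cycle genes passed upward and ribosomal protein genes downward as lists by camera, while by limma 0 members of either passed, over all transcripts or adjusted over the list alone, with 2 of each at an unadjusted p under 0.05. The 46 cell cycle genes had a median of 0.14 (camera adjusted p = 0.0193, adjusted p = 0.816 with an estimated correlation), with Nusap1, Mcm4, Rrm2 and Pcna at 0.33, 0.21, 0.46 and 0.16 (0.17, 0.13, 0.17 and 0.08 without wild-type replicate 2). The 61 ribosomal protein genes had a median of -0.08 (camera adjusted p = 0.000568, adjusted p = 0.662 with an estimated correlation), with Rpl34, Rps20, Rps3 and Rplp1 at -0.31, -0.20, -0.17 and -0.14 (-0.17, -0.12, -0.10 and -0.06 without wild-type replicate 1), and a median of 0.01 under quantile normalization. The cell cycle median was -0.21 with the erythroid covariate and -0.01 without wild-type replicate 2, 0.23 without wild-type replicate 3 and 0.22 without wild-type replicate 4, and the list did not pass without wild-type replicate 1 or TTPΔARE replicate 3 (adjusted p = 0.0936 and 0.134). The ribosomal list did not pass without wild-type replicate 1 or TTPΔARE replicate 2 (medians -0.03 and -0.04, adjusted p = 0.0936 and 0.102).

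**Figure D3:**
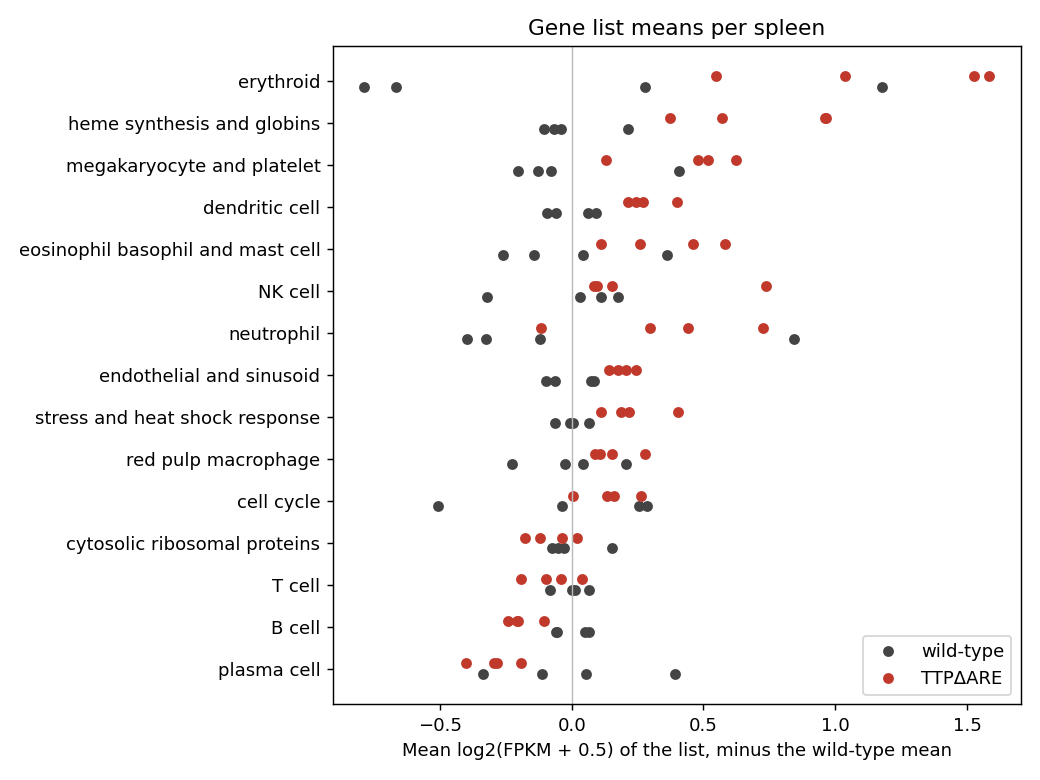
Mean log2(FPKM + 0.5) of each of the 15 lists that passed camera, minus the wild-type mean (x axis, log2), with a point per spleen, wild-type in grey and TTPΔARE in red. The 4 TTPΔARE spleens lay apart from the 4 wild-type spleens for 5 of these lists, and for the erythroid list wild-type replicate 3 lay among the TTPΔARE spleens.

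Reported TTP target mRNAs did not shift as a group. Of 44 listed, 32 were tested, and by limma 0 of 32 passed, over all transcripts or adjusted over the list alone. At an unadjusted p under 0.05 were 7 of the 32, against 3503 of all 16608 transcripts tested. The median was -0.01 (camera adjusted p = 0.428), and -0.090 to 0.0078 with 1 spleen left out. Pim3 and Il1a had log2 values of -0.23 and -0.24, Ccl4 0.41 (0.26 without wild-type replicate 4) and Irf8 0.10 (0.05 without wild-type replicate 3). Of 34 cytokine and chemokine genes Ccl24, Il12a (log2 0.58) and Tnfsf14 (0.35) rose and Ccl21a and Cxcl13 (-0.56) fell, the same number when adjusted over the list alone, while Ltb stood at 0.06 (camera adjusted p = 0.653). Of 36 immediate early genes Dusp2 (-0.47), Nr4a1 and Btg2 (-0.28) fell and Btg1 stood at 0.20, with 5 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.190). By limma 0 of 26 NF-κB genes passed in either adjustment and 5 had an unadjusted p under 0.05, with Nfkbiz, Cd40, Nfkbid and Nfkbia at -0.32, -0.27, -0.19 and 0.11 (camera adjusted p = 0.507). Isg20 (log2 0.66) and Rsad2 (0.77) rose among 47 interferon-stimulated genes, 3 when adjusted over the list alone, with Gbp5 at 0.23 and Sp100 at -0.20 (camera adjusted p = 0.670).

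Genes of mRNA decay moved little. Xrn2, a nuclear 5′ to 3′ exonuclease, fell by 0.28 on the log2 scale as 1 of 50 decay genes, and 1 when adjusted over the list alone, with Ddx6, Dcp1b and Pabpc1 at -0.23, -0.27 and 0.14 (camera adjusted p = 0.130). By limma 0 of 22 genes of other AU-rich element binding proteins passed in either adjustment and 4 had an unadjusted p under 0.05, with Zc3h12a, Hnrpdl, Tia1 and Hnrnpa2b1 at -0.24, -0.27, -0.21 and -0.01 (camera adjusted p = 0.190). The 3 TTP family genes gave a camera adjusted p of 0.190, and 0.0349 without TTPΔARE replicate 3, with 1 rising and 2 falling when adjusted over the list alone. Of 50 oxidative phosphorylation genes 0 passed in either adjustment and 2 had an unadjusted p under 0.05, with Uqcrfs1, Ndufa8, Ndufb3 and Atp5b at -0.19, 0.20, -0.16 and 0.01 (camera adjusted p = 0.670). Their median was 0.002 while the mean, -0.003, and the test direction were below 0.

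The AU-rich element test gave no shift. Genes with at least 2 TATTTAT heptamers in the longest annotated 3′ UTR, 1253 of them, had a median log2 value of 0.002 against 0.008 for 10693 others, and 932 genes with a TTATTTATT nonamer a median of -8.24e-05 against 0.008 for 11014 others. The limma camera adjusted p was 0.582 for each motif. Of the heptamer genes 26 rose and 29 fell, and of the nonamer genes 9 rose and 16 fell.

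Genes near Zfp36 and those of other tissues served as checks. Of 50 listed genes near Zfp36 only Zfp36 itself rose, with Map4k1, Sars2 and Rps16 at -0.21, -0.30 and 0.01, and 2 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.507). Ffar1 and Cd22, which fell and lie within 10 Mb of Zfp36, were not on this list. Of 20 stromal and fibroblast genes Wt1 rose (log2 0.59) and Ccl21a, Cxcl13 and the proteoglycan Dcn (-0.48) fell, while Ccl19 stood at -0.22, with 5 rising and 3 falling when adjusted over the list alone (camera adjusted p = 0.510). By limma 0 of 6 adipose genes passed in either adjustment, and 0 had an unadjusted p under 0.05, with Cyp2e1 at -0.83 (SE 0.668), Adipor2 at 0.06 and Cfd at 0.39 (camera adjusted p = 0.996). The adipose median was 0.01 and the mean -0.09. Of the 20 pancreas genes measured only 1 passed the filter on low values, and the highest mean was 4.15 FPKM, for Cela1. The Y-linked genes Kdm5d, Ddx3y, Uty and Eif2s3y were expressed in all samples and had log2 values of -0.21, -0.09, -0.05 and -0.003, and 0 passed in either adjustment, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.222).

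Of the 29 lists tested 15 passed camera with a preset correlation of 0.01, 11 up and 4 down. With the erythroid covariate 6 passed, the cell cycle list in the other direction, and the stress, plasma cell, NK cell, macrophage, mast cell, megakaryocyte and T cell lists did not (adjusted p = 0.0525, 0.0666, 0.0993, 0.287, 0.419, 0.0558 and 0.974), nor did the neutrophil list (0.0666) or the erythroid list itself (0.480). Their medians were then 0.10, -0.23, 0.18, 0.06, 0.17, 0.14 and -0.01, and -0.35 and -0.04. The outcome of the erythroid list was fixed in advance, since the covariate was the mean of that list. With an estimated correlation per list 0 passed (smallest adjusted p 0.528), with 1 at an unadjusted p under 0.05. By fry's directional test 0 passed and 8 had an unadjusted p under 0.05, while by its test of change in either direction, which compares a list with no other genes, 19 passed. By an exact permutation test of per-sample list means 0 passed (smallest adjusted p 0.138) and 6 had an unadjusted p under 0.05.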

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

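All tests of explanations in this part, those of other splits of the samples included, were chosen after the results were seen.

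The 664 transcripts that passed were set against variants that travel with the Zfp36 allele on chromosome 7. Within 10 Mb of Zfp36 lay 1.55% of the called symbols, 8 of 517 counted by the most abundant transcript of each symbol in the fit of all transcripts, and 3.74% of the 214 tested symbols there were called against 4.17% elsewhere (odds ratio 0.892, 95% interval 0.378 to 1.80, Fisher's exact p = 1). Variants near Zfp36 that act on neighbouring genes therefore cannot account for the bulk of the calls, while a flanking variant acting on distant genes stays open. Ffar1 and Cd22, which fell, lie in this window, at 30860568 and 30865404 on chromosome 7. For them a variant acting on neighbouring genes stays open too. Of the 35 splits of the 8 samples into 4 and 4, only 1, the real one, gave 664 calls, and the highest of the others gave 111. This argues against chance but cannot exclude it, since 0.0286 is the smallest share that 35 splits allow.

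For the gene lists 4 of 35 splits gave as many as the real 15, up to 19, so chance cannot be excluded. No split passed fewer than 4 lists. Wild-type replicates 1 and 3 with TTPΔARE replicates 3 and 4, set against the rest, passed 15 lists and 0 transcripts. Camera at the preset correlation thus passed many lists in groupings that do not follow genotype. For the AU-rich element tests 26 of 35 gave a p as small as the real 0.454, down to 4.73e-05.

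By camera the erythroid and globin lists were higher and the B cell list lower, where 1 of 27, 7 of 20 and 3 of 18 genes passed (adjusted p = 0.538, 0.528 and 0.528 with an estimated correlation). If blood left in the organ were the source, genes of nucleated precursors would not rise with the globins. The precursor genes differed by log2 1.29 (SD 1.03 in wild-type and 0.534 in TTPΔARE, n = 4 each, exact permutation p = 0.0857) and the globins by 1.18 (exact permutation p = 0.0286). Wild-type replicates 1 to 4 stood at -0.75, -0.88, 1.32 and 0.32 for the precursors and at 0.25, 0.48, -0.31 and -0.43 for the globins, opposite in sign in each. With the erythroid covariate Hba-a1, Hba-a2, Hbb-b1 and Beta-s stood at log2 1.39, 1.40, 1.36 and 1.41 and did not pass (limma adjusted p = 0.104 to 0.105). In TTPΔARE the precursors ran from 0.58 in replicate 2 to 1.71 in replicate 3, and the globins from 0.85 to 1.46. Both ranked the TTPΔARE spleens in the same order. The precursors thus went with the globins among TTPΔARE spleens but not among wild-type spleens. Blood left in the organ and more erythropoiesis therefore cannot be told apart. If more erythroid cells only diluted the rest, no gene confined to other cell types would rise. By limma 13 of 179 genes of 11 cell type lists rose and 11 fell. Of those that rose, only Esam, on the dendritic and endothelial lists, and Itgae, on the dendritic list, passed with each spleen left out. The others lost the call with 2 to 7 of the 8 spleens left out in turn. Whether the listed genes are confined to their cell types was not tested. If they are, Esam and Itgae argue against dilution alone, while dilution beside changes in those cell types stays open. The count of genes that rose was the last of 3 tests tried: the SD of the 11 list differences, 0.222, was as large in 3 of 35 splits, and 2 lists parted without overlap each way in 1 of 35, but in 2 of 35 without the monocyte list, whose groups lay 0.000866 apart. With the erythroid mean as a covariate the median absolute log2 change of the called transcripts went from 0.41 to 0.37 and the median SE from 0.0821 to 0.109. How far each of these ended the calls was not tested.

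Single samples stood far from the other 3 of their group in 26 of 350 groups of values. For normal values chance gives 17.5. FPKM need not be normal and the genes share the same spleens, so whether 26 exceeds chance was not tested. In TTPΔARE replicate 3, Zfp36l2 was at 46.4 FPKM (others 31.3 to 33.7), Hsph1 at 28.4 (16.7 to 18.6), Wt1 at 6.55 (4.90 to 5.03) and Chordc1 at 30.1 (25.2 to 25.9). In TTPΔARE replicate 4, Rps20 was at 389.7 FPKM (333.1 to 342.5), Klra8 at 7.10 (3.47 to 3.77) and Gzma at 44.0 (19.0 to 22.1), the mean of the NK cell list at 0.74 on the log2 scale (0.08 to 0.15) and that of the stromal list at -0.19 (0.08 to 0.12). In TTPΔARE replicate 2, Ccl24 was at 2.66 FPKM (3.55 to 3.69), Gata2 at 2.37 (2.66 to 2.69) and the depth at 29.1 M fragments (31.7 to 32.2). In TTPΔARE replicate 1, Cfd was at 3.54 FPKM (0.205 to 0.670).

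Among wild-type spleens, replicate 1 had Nfkbid at 10.08 FPKM (others 11.07 to 11.13), Hnrpdl at 51.3 (39.5 to 40.2), Rpl34 at 412 (276.0 to 280.9), Rps3 at 330.9 (274.9 to 280.4) and Kdm5d at 7.32 (8.09 to 8.23). Replicate 2 had Dsc3 at 1.51 FPKM (1.91 to 1.96), Cyp2e1 at 9.83 (0.300 to 0.723) and Flt3 at 10.94 (9.07 to 9.20). Replicate 3 had Fech at 17.4 FPKM (13.1 to 13.4), Cacybp at 13.2 (14.2 to 14.4) and Dnaja4 at 3.21 (2.48 to 2.60). Replicate 4 had Esam at 5.34 FPKM (6.02 to 6.11) and the mean of the stromal list at -0.10 on the log2 scale (0.03 to 0.04).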

How the results depend on the processing

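Using 1 transcript per symbol and the permutation test of list means were chosen after the data were seen. Of the 664 transcripts, 660 passed with a pseudocount of 0.1, 661 with 1, 641 with median-of-ratios scaling, 572 with quantile normalization, 530 with no variance trend, 650 with a robust variance, 660 with sample weights, 608 with a filter of 1 FPKM and 459 with no filter, where more were tested. With 1 transcript per symbol 239 were higher and 215 lower, as fewer were tested, and at an adjusted p under 0.1 there were 726 higher and 636 lower. With the erythroid covariate 0 were higher and 2 lower by limma, and 1744 had an unadjusted p under 0.05. Leaving out 1 spleen gave 94 to 446 higher and 104 to 331 lower. No paired analysis was possible because the labels give no shared numbers for the mice, and replicates were numbered in the order of the samples. At 0.5 FPKM a transcript of the median length, 2664 bases, rests on about 37.7 fragments at the lowest depth, and shorter ones on fewer.

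Zfp36 stayed higher in all alternatives, at log2 0.34 to 0.45 when a spleen was left out. The exact permutation p was then 0.0571 with any 1 wild-type replicate, or TTPΔARE replicate 1 or 3, left out. The groups still did not overlap in any of these, and with fewer assignments each one counts for more. Of the 29 lists 6 passed with the erythroid covariate, 0 with an estimated correlation, 0 by fry's directional test and 0 by the permutation test of list means, with 1, 8 and 6 at an unadjusted p under 0.05 in the last 3. The B cell median of -0.18 and the erythroid median of 1.18 then had adjusted p of 0.528 and 0.538 with an estimated correlation, 0.0530 and 0.168 by fry and 0.138 and 0.276 by permutation. For the counts, calls and directions that changed, the cause was not tested unless a number tested is named.

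The adipose median against its test direction was 0.0098 with a pseudocount of 0.1, 0.051 with no filter, 0.0064 with median-of-ratios scaling, -0.0039 with quantile normalization, 0.032 with sample weights, 0.41 with the erythroid covariate and 0.012 by fry. With quantile normalization the ribosomal median was 0.011, that of oxidative phosphorylation 0.019, Hnrnpa2b1 0.034 and Eif2s3y 0.021. With sample weights oxidative phosphorylation was at 0.037 and Ear2 at 0.012. With a minimum of 1 heptamer the median minus that of the other genes was 0.0056. With the erythroid covariate the medians were 0.035 for NF-κB, -0.21 for cell cycle, -0.0067 for T cells, -0.35 for neutrophils and -0.044 for the erythroid list itself, whose mean was the covariate, and Mcm4 was at -0.0084, Rrm2 at -0.14, Pcna at -0.013, Atp5b at -0.048, Rps16 at -0.021, S100a9 at -0.42, Cyp2e1 at 0.35, Ddx3y at 0.013, Uty at 0.062 and Eif2s3y at 0.084.

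Leaving out 1 spleen gave list medians of -0.0030 to 0.048 for cytokines, -0.059 to 0.032 for interferon-stimulated genes, -0.0098 to 0.23 for cell cycle, -0.035 to 0.052 for oxidative phosphorylation and -0.23 to 0.089 for adipose genes. Medians also crossed 0 for reported TTP targets (-0.090 to 0.0078), NF-κB (-0.024 to 0.013), genes near Zfp36 (-0.040 to 0.0067), monocytes (-0.045 to 0.031) and stromal genes (-0.0036 to 0.16). The median minus that of the other genes was -0.021 to 0.0086 for the heptamer and -0.016 to 0.0046 for the nonamer. Among genes, leaving out 1 spleen gave -0.018 to 0.012 for Hnrnpa2b1, -0.036 to 0.053 for Atp5b, -0.043 to 0.082 for Rps16, -0.068 to 0.33 for Gzma, -0.041 to 0.070 for H2-Aa, -0.091 to 0.38 for S100a9, -0.18 to 0.076 for Ear2, -1.20 to 0.033 for Cyp2e1, -0.17 to 0.74 for Cfd, -0.10 to 0.042 for Uty and -0.16 to 0.079 for Eif2s3y. Of 1192 gene values with 1 spleen left out, 957 kept their direction and side of the threshold, 194 no longer passed, 12 passed newly and 29 turned. Of the 72 genes examined that did not pass, 34 moved by over 1.5 times with a spleen left out. Of 77 called transcripts named in the text, 55 kept the call in each of the 9 or 10 processing alternatives run for them, the covariate aside, and 31 with each spleen left out. The call was lost with 6 or 7 of the 8 spleens left out in turn for Apol11b, Ccl21b, Btg2, Hsph1, Hspa8, H2-Ob, Klra8, Xcr1, Treml1, Cacybp, Cd1d1, Dcn, Flt3, Gimap3, Gimap8, Kdr and Sox18.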

Other observations

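The tests and genes in this part were chosen after the results were seen.

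Chordc1 and 6 further genes of co-chaperones and chaperone relatives rose in TTPΔARE spleen, picked because they had passed, so their number says nothing of such genes as a group. Chordc1 rose from 19.6 ± 0.771 to 26.7 ± 2.25 FPKM (SD, n = 4 each; log2 0.44, limma adjusted p = 0.00776), Fkbp4 by log2 0.48, Dnaja4 by 0.47, Hspa4l by 0.45, Ahsa2 by 0.39, St13 by 0.32 and Cacybp by 0.28. Gimap genes encode GTPases of lymphocytes, and 4 of 8 tested fell while 4 did not pass: Gimap6 from 92.3 ± 6.09 to 72.8 ± 4.59 FPKM (log2 -0.34), Gimap1 and Gimap8 (both -0.27) and Gimap3 (-0.24). Of 12 circadian clock genes 0 passed by limma and 2 had an unadjusted p under 0.05, with log2 values of -0.17 to 0.21 and a smallest adjusted p of 0.215.

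Cd55, which shields cells from complement, fell from 61.95 ± 2.03 to 39.7 ± 3.92 FPKM (SD, n = 4 each; log2 -0.64, limma adjusted p = 0.00360). Tnfrsf13b, which encodes the receptor TACI (log2 -0.31), and the most abundant Ccr6 transcript (-0.72) fell too, while Cd1d1 (0.31) and Myof (0.47) rose. Plaur, the urokinase receptor gene, fell from 13.5 ± 0.970 to 7.42 ± 0.263 FPKM (log2 -0.82, SE 0.0617, limma adjusted p = 0.000584), and Stac2 from 4.203 ± 0.158 to 2.18 ± 0.162 FPKM (log2 -0.81). With the erythroid covariate they stood at log2 -0.79 (SE 0.0880) and -0.85 (SE 0.0944), both at a limma adjusted p of 0.0188. None of these genes was tested as a set, since they were picked from their values.

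Few rising genes held the AU-rich nonamer. Of 932 nonamer genes 9 rose, 0.966%, against 2.40% of 11014 others (Fisher's exact p = 0.00283, adjusted p = 0.0113 over 4 tests, the other 3 of which had adjusted p of 0.451 to 0.802). Sets matched on 3′ UTR length, base composition and expression had a median of 21 rising genes (95% of 10000 draws held 13 to 29, one-sided permutation p = 0.00150). Those matched on length and expression held 13 to 30 (one-sided permutation p = 0.00180). A logistic fit on all 3 properties gave the nonamer a coefficient of -0.94 (SE 0.344). The shortage thus remained after matching on these properties, though these tests treat genes as independent. In 2 of 35 splits as few nonamer genes lay among the 300 genes at an end of the ranking (9 in the real split, 7 in the fewest of the others), so chance cannot be excluded. The share that fell was no higher, 1.72% against 1.89%, and the AU-rich element tests fixed earlier gave no shift.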
